A study of Homo sapiens with 8 samples.

How the data were processed

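Gene expression was measured on 8 Affymetrix HG-U133 Plus 2.0 arrays of MCF-7 cells in 6 groups. The deposited values were on a log2 scale as taken here from their range and the usual convention for this chip, since the base is not stated by the sources used. The authors had centred the values per probe set on a baseline that was not the median of these arrays, as the deposited values show. The median over the 8 arrays was 0 (within 1e-05) in only 9.16% of probe sets. Differences between arrays within a probe set are therefore interpretable and levels are not. The summarization, background correction and baseline are not given in the sources used here. Array medians over genes ran from -0.03 to 0.12.

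Of 54675 probe sets, 62 were control probe sets and were left out of the tests. The platform annotation, which can be old, gave 1 gene symbol for 41091 probe sets, several for 1801 and none for 11721. Symbols were updated through the Entrez ID for 41037 probe sets. Probe sets with 1 symbol gave 19775 genes, of which 10523 had several probe sets. A gene's value was the mean of its probe sets. The rule planned before the data were examined, the probe set of highest mean, carries no meaning for centred values and was run as an alternative. Of 24 genes called for E2-BSA that had several probe sets, 2 had a probe set of the opposite sign. No filter on dim genes was applied, because centred values hold no level.

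Tests were run in R 4.3.3 with limma 3.58.1. A mean per group was fitted to all 8 arrays, with 2 residual degrees of freedom, followed by eBayes and Benjamini-Hochberg adjustment over all genes at 0.05. Groups with 1 array were assumed to vary like the pairs. After the data were seen, array set was added as a block, which left 1 residual degree of freedom. Gene lists, 34 in number with 474 of 537 genes measured, were written before the data were examined. They were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The version with an estimated correlation works on the residual degrees of freedom, 2 as designed and 1 with array set, so it could hardly call a list. Random lists, 10000 of the same size, described medians on single arrays and were not matched on level, which centred values do not hold. Counts of 2-fold differences took genes with a difference of at least 1 and no overlap between the arrays of the groups.

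Genes were named by a rule set before the data were examined: 12 per direction for E2-BSA against control and 8 for each other comparison, by size among genes past the threshold, with the places left filled by the largest differences without overlap. List members were named by size. The fits were tested on simulated data with 19775 genes, 200 of them changed, in 20 draws for E2-BSA against control. As designed the fit recovered 0% of 2-fold and 29.2% of 4-fold changes with no false calls. With array set it recovered 99.9% and 100%, but 12.6% of its calls were false on average and at most 17.4%. The simulated changes were equal in both array sets, and the noise was independent between genes, with SDs taken from the fit. These shares therefore do not give the error rate of the calls in the data.

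Alternatives were quantile normalization, centring each array on its median, the probe set of highest mean, every probe set, robust eBayes, only the arrays of the groups compared, and leaving out each control and E2-BSA array. The filter at the 70th percentile, the intensity trend and other pseudocounts were not run, because the values are centred logs. Figures were drawn with matplotlib 3.10.9.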

Results

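The series measured gene expression in MCF-7 cells, an estrogen receptor positive human breast cancer cell line, on 8 single-colour Affymetrix arrays covering 19775 named genes. The cells were given estradiol (E2), estradiol coupled to the carrier protein bovine serum albumin (E2-BSA), or the carrier alone (BSA), each at 1 µM for 3 h. An antagonist given in the labels only as ICI, or G15, an antagonist of the G protein-coupled estrogen receptor GPER1, was added at 10 µM to E2-BSA in 1 group each. Control and E2-BSA had 2 arrays each, and E2, BSA, E2-BSA+ICI and E2-BSA+G15 had 1 array each. Nothing in the labels says that the arrays of a group came from separate cultures. As designed, the p-values measure the spread between the control arrays and between the E2-BSA arrays, which may be technical. Groups with 1 array add nothing to it, so their SEs and p-values hold no spread of their own array. The number of arrays limits the precision of every value. All values are differences of deposited log values, taken as log2.

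The arrays fell into 2 sets that did not follow the treatments. Control 1, E2 and E2-BSA 1 formed set 1, and control 2, E2-BSA 2, E2-BSA+ICI, E2-BSA+G15 and BSA formed set 2. Without BSA, the SD across genes of the difference between 2 arrays was 0.178 to 0.248 within a set and 0.408 to 0.457 between sets. The 2 control arrays differed at least 2-fold at 606 genes and the 2 E2-BSA arrays at 645 genes. Each comparison could be made within a set, so counts are given both from the fit as designed and with array set in the model. The differences and SEs of single genes come from the model with array set. Its 1 residual degree of freedom is the disagreement of the E2-BSA response between the 2 sets. In eBayes a prior SD shared by all genes, 0.114 with 6.3 degrees of freedom, outweighs it. These SEs therefore lean more on the other genes than on the gene itself. As designed the SE of RBM24 for E2-BSA against control was 0.83, against 0.14 with array set. CYP24A1 for E2 against control was 3.52 ± 1.45 as designed, against 2.29 ± 0.19 with array set. The model with array set was chosen after the data were seen. In simulated data for E2-BSA against control, 12.6% of its calls on average were false, above the nominal 5%. The word rose or fell is used below only for genes past an adjusted p of 0.05 in that model.

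E2-BSA was compared with control to ask which genes respond to the conjugate within 3 h. The largest rises were in RBM24, an RNA-binding protein gene (log2 difference 3.18 ± 0.14, SE, 2 against 2 arrays), EGR3, an immediate early transcription factor (2.86 ± 0.18), SMTNL2 (2.63 ± 0.11) and the kinase gene SGK1 (2.20 ± 0.11). MYC rose by 1.99 ± 0.22, FOS by 1.86 ± 0.13, HEY2 by 1.82 ± 0.14 and SIGLEC15 by 1.77 ± 0.13. PMAIP1, CXCL12, KCNK6 and PGR, the progesterone receptor gene, rose by 1.69, 1.66, 1.63 and 1.63. TNFRSF11B, which encodes osteoprotegerin, fell by 1.25 ± 0.11. Within the sets, the difference for RBM24 was 2.94 in set 1 and 3.42 in set 2, for EGR3 3.26 and 2.46, for PGR 1.89 and 1.36, and for TNFRSF11B -1.29 and -1.21.

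As designed, limma with Benjamini-Hochberg adjustment called 0 of 19775 genes in E2-BSA against control, with 297 genes at an unadjusted p below 0.05. With array set in the model limma called 57 genes, 55 higher and 2 lower. The second lower gene was PSMB9, an immunoproteasome subunit gene. Quantile normalization ended all 57 calls, and the smallest adjusted p from limma was then 0.172. The sign of all 57 differences stayed and their median size went from 1.09 to 1.28, while the median residual SD over genes went from 0.082 to 0.107. With 1 probe set per gene, the one of highest mean, 17 genes were called. Differences of at least 1 in both sets were seen for 26 genes upward and 1 downward.

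**Figure D1:**
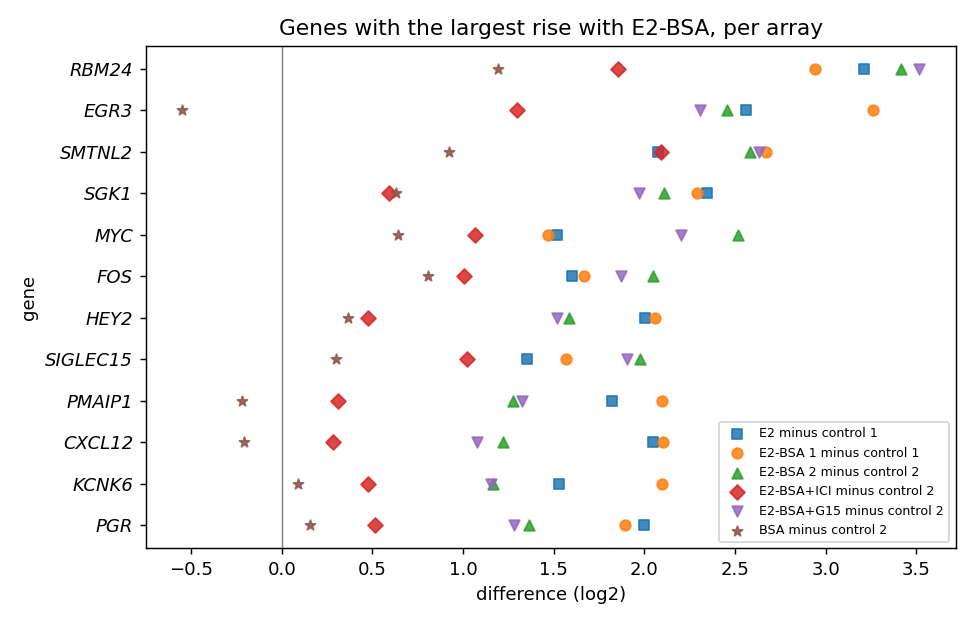
Log2 difference (horizontal axis) of the 12 genes with the largest rise with E2-BSA, one row per gene, with 1 point per array against the control of its own array set. The E2, E2-BSA and E2-BSA+G15 points lie to the right of the BSA points for every gene, and RBM24 reached 3.42 with E2-BSA 2 and 1.19 with BSA.

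Lists fixed before the data were examined are given next for E2-BSA against control. None of their calls held with an estimated correlation (adjusted p from limma's camera 0.641 to 0.923 as designed), a version with too few residual degrees of freedom to decide. All 37 measured estrogen-induced genes were higher, with a median difference of 0.74, and 12 rose over all genes tested, 33 when adjusted over the list alone. EGR3, MYC, FOS and HEY2 led the list. Of 28 immediate early genes 4 rose, 8 when adjusted over the list alone, with KLF4 at 1.10 ± 0.12 after EGR3, MYC and FOS, but their median was only 0.02. FOS was the only 1 of 13 genes linked to GPER signalling that rose. Ribosome biogenesis genes were higher in 13 of 15, with RRS1 at 0.74, WDR43 at 0.64 and POLR1C at 0.62, and 0 of them rose over all genes tested while 5 did when adjusted over the list alone. TGF-beta and BMP response genes were lower in 11 of 12, with ID1 at -1.05, ID2 at -1.02 and ID3 at -0.75, and 0 fell over all genes tested while 4 did when adjusted over the list alone. These differences rested mainly on set 1: ID1 was at -1.51 in set 1 and -0.60 in set 2, ID2 at -1.38 and -0.65, and ID3 at -1.23 and -0.27, and on the BSA array ID1, ID2 and ID3 were at -0.01, -1.10 and 0.13 against control 2. Estrogen-repressed genes were lower in 14 of 17, led by ID1 and by CCNG2 at -0.66, and were not called as designed (adjusted p from limma's camera 0.114) but were after quantile normalization (0.0158) and with array set (0.000121, adjusted p = 0.868 with an estimated correlation).

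In camera with a preset correlation, 6 lists were called as designed and 8 with array set. The adjusted p from limma's camera was 1.23e-43 for estrogen-induced genes (adjusted p = 0.641 with an estimated correlation), 0.000158 for ribosome biogenesis (adjusted p = 0.923 with an estimated correlation) and 0.000116 for the TGF-beta and BMP list (adjusted p = 0.709 with an estimated correlation). For the immediate early list it was 0.0325, for genes linked to GPER signalling 0.00289 and for S phase genes 0.0325 (each adjusted p = 0.923 with an estimated correlation). With array set the estimated correlation was 0.303 for estrogen-induced, 0.733 for ribosome biogenesis, 0.394 for TGF-beta and BMP and 0.326 for S phase genes. For immediate early genes it was -0.032 and for genes linked to GPER signalling 0.077. These estimates rest on 1 residual degree of freedom. Where they exceed the preset 0.01, the p-values of the preset version may be far too small, in the other comparisons as well. No list was called in any of the 7 comparisons with an estimated correlation. That version works on the few residual degrees of freedom of the fit, so it could hardly call any list. With array set, the estrogen-induced list, with all 37 genes higher, had an unadjusted p of 0.126 from this version of limma's camera. Its lack of calls therefore does not decide whether a list moved. The receptors ESR1, ESR2 and GPER1 differed by -0.09 ± 0.11, 0.10 ± 0.12 and 0.02 ± 0.11, none past the threshold.

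E2 was compared with control as the response to the uncoupled steroid. RBM24 rose by 3.33 ± 0.18 (1 against 2 arrays), EGR3 by 2.36 ± 0.24, CYP24A1, the vitamin D 24-hydroxylase gene, by 2.29 ± 0.19 and SMTNL2 by 2.05 ± 0.14. KIT rose by 1.88 ± 0.20, PGR by 1.87 ± 0.19 and SIGLEC15 by 1.46 ± 0.17, and TNFRSF11B fell by 1.79 ± 0.14. All 37 estrogen-induced genes were higher, with a median of 0.80 with array set, and 6 rose over all genes tested, 31 when adjusted over the list alone. MYC at 1.78 ± 0.29 and CXCL12 at 1.83 ± 0.26 did not pass over all genes.

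As designed, limma called 0 genes for E2 against control, with 345 at an unadjusted p below 0.05, and with array set 21, 20 higher and 1 lower. Quantile normalization ended these calls too, and 3 genes were called with the probe set of highest mean. For the estrogen-induced list the adjusted p of limma's camera was 1.35e-32 (adjusted p = 0.773 with an estimated correlation), and for ribosome biogenesis genes, higher in 15 of 15, it was 9.37e-08 (adjusted p = 0.773 with an estimated correlation). Camera also called immediate early, estrogen-repressed, MAPK feedback, GPER-linked and splicing factor genes, and the last 3 were not called with array set in the model. As designed, a group of 1 array is compared across both sets, so its list tests include part of the difference between the sets. These 3 lists were lower in set 2, with medians of -0.46, -0.495 and -0.268 in the control pair. In the E2-BSA pair the medians were -0.309, -0.333 and -0.316. The same limit holds below for splicing factor genes with BSA and GPER-linked genes with G15.

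The free and the coupled steroid were compared directly at the same 1 µM and 3 h. Of the 21 genes called with E2, 20 were among the 57 called with E2-BSA, 19 higher and 1 lower in both. Independent lists would share 0.056 higher genes, and simulated unchanged groups against the same controls shared a median of 2 genes and at most 7 in 50 draws. Part of the overlap may come from the shared controls. The exception, CYP24A1, was called with E2 but its difference between E2-BSA and E2 was not called. Across genes, which are not independent replicates, the 2 responses correlated with r = 0.545 (covariance 0.0285). Simulated unchanged groups gave r = 0.407 (covariance 0.00687), but the simulation held no difference between the array sets. The E2 value against both controls contains that difference, so the simulated r is not a matched reference. When no array was shared, r was 0.315.

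**Figure D2:**
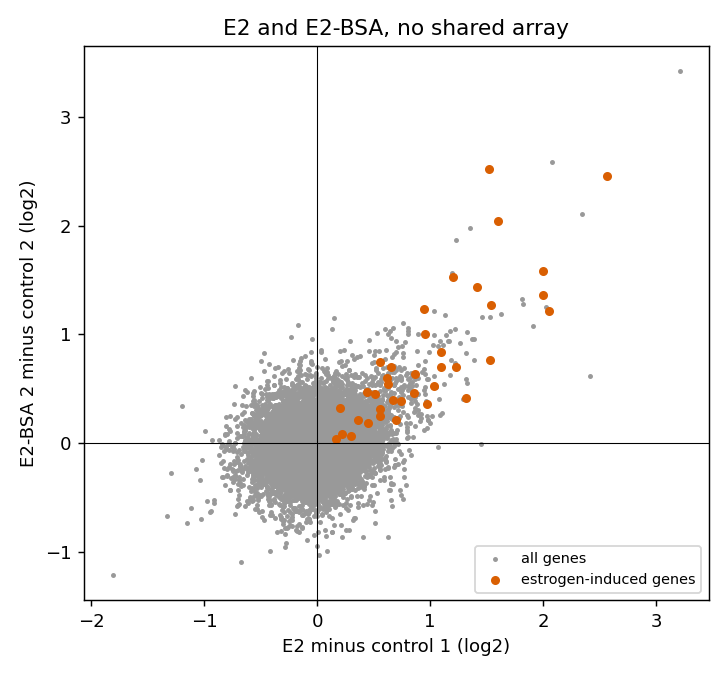
Log2 difference of E2 from control 1 (horizontal axis) against that of E2-BSA 2 from control 2 (vertical axis), 1 point per gene, with no array in common. The 37 estrogen-induced genes, in orange, lie above 0 on both axes, and r across all genes was 0.315.

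Among 42 genes at least 1 higher in E2-BSA 2 than in control 2, the median difference from control 1 was 1.23 with E2 and 1.21 with E2-BSA 1. E2-BSA 1 minus E2 had a median of 0.00 over these genes, with a range of -0.43 to 0.70, and 21 of 42 lay above 0. For PGR the difference of E2-BSA from E2 was -0.24 (95% interval -0.68 to 0.21), and for ESR1 0.13 (95% interval -0.21 to 0.46). As values not past the threshold, E2-BSA minus E2 with array set was -0.89 ± 0.14 for PSMB9 and -1.07 ± 0.26 for ID1, which encodes an inhibitor of DNA binding. As designed limma called 0 genes between E2-BSA and E2, with 141 at an unadjusted p below 0.05, and 0 with array set, with 806. These counts do not show that the 2 forms act alike. The TGF-beta and BMP list was lower with E2-BSA than with E2, with an adjusted p from limma's camera of 0.00948 (adjusted p = 0.89 with an estimated correlation). Camera called 5 further lists as designed, immediate early, MAPK feedback, SRF and YAP, ribosome biogenesis and splicing factor genes, none of which was called with array set.

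BSA was compared with control as the carrier alone. The BSA array stood apart from the other arrays of its set, with an SD of differences of 0.354 to 0.416, and the median of all genes was 0.12 higher than in control 2. Its SD over genes was 0.505, against 0.304 to 0.336 on the rest of set 2, a spread that the SEs below do not hold. The 24 poly-A spike-in probe sets, whose RNA does not come from the cells, had a median of 0.32 for BSA minus control 2. ACTL6A, a chromatin remodelling subunit gene, fell, with a log2 difference of -3.82 ± 0.15 (SE, 1 against 2 arrays), as did PPIL4 (-3.19 ± 0.15), TMEM69 (-3.09 ± 0.15), ZNF623 (-2.85 ± 0.14) and RNF11 (-2.60 ± 0.15). UCN rose by 1.57 ± 0.20, TNFSF13 by 1.21 ± 0.14 and CALML5 by 1.05 ± 0.14. The estrogen-induced list had a median of 0.01 against control 2, with 19 of 37 genes above 0. With array set its median was 0.10, with 25 genes higher and 12 lower, of which 2 rose and 3 fell, and camera did not call it (adjusted p from limma 0.955). After quantile normalization camera called this list higher, with an adjusted p from limma of 0.00285, and of 7.72e-08 with array set.

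As designed limma called 0 genes for BSA against control, with 2498 at an unadjusted p below 0.05. With array set it called 2435 genes, 1428 higher and 1007 lower. After each array was centred on its median the split was 829 higher and 1422 lower, and after quantile normalization 0 genes were called. Splicing factor genes were lower in camera, with an adjusted p from limma of 0.0235 (adjusted p = 0.97 with an estimated correlation), and not called with array set.

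E2-BSA was compared with BSA to set the conjugate against its carrier. EGR3 was higher with E2-BSA by 3.21 ± 0.24 (2 against 1 arrays), RBM24 by 2.11 ± 0.18 and PGR by 1.34 ± 0.19, all past the threshold with array set. GREB1, a classical estrogen receptor target, was higher by 2.35 ± 0.27. Of the 37 estrogen-induced genes 17 were higher past the threshold over all genes, and 25 when adjusted over the list alone. ACTL6A, TMA16 and PPIL4, which were low on the BSA array, were higher with E2-BSA by 3.73, 2.83 and 3.18. Metallothionein and zinc response genes were lower in 8 of 8, led by MT1F at -0.71 and MT2A at -0.65, of which MT1G alone, at -0.56, passed over all genes. These genes were high on the BSA array, with a median of 0.54 against control 2, while their median for E2-BSA against control was -0.09 and not called.

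As designed limma called 0 genes between E2-BSA and BSA, with 2463 at an unadjusted p below 0.05, and with array set 2213, 995 higher and 1218 lower. After median centring the split was 1472 higher and 633 lower, and quantile normalization ended all calls. The estrogen-induced list had an adjusted p from limma's camera of 4.46e-16 (adjusted p = 0.887 with an estimated correlation). Camera also called the immediate early, splicing factor and metallothionein lists, the last with an adjusted p from limma of 0.0273 (each adjusted p = 0.887 with an estimated correlation). With array set the metallothionein and splicing factor calls were lost (adjusted p from limma's camera 0.0743 and 0.0614).

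E2-BSA+ICI was compared with E2-BSA to ask which E2-BSA genes are lower with that antagonist. Among 60 genes at least 1 higher in E2-BSA 1 than in control 1, the median difference from control 2 was 0.95 in E2-BSA 2, 0.40 with ICI, 0.90 with G15 and 0.10 with BSA. ICI was lower than E2-BSA 2 at 57 of the 60 genes, with a median of -0.58, below all 10000 random lists of that size as a description of these arrays. ICI minus E2-BSA with array set was -1.45 ± 0.18 for RBM24, -1.45 ± 0.14 for RHOBTB1, -1.36 ± 0.24 for EGR3 and -0.98 ± 0.19 for PGR, none of them past the threshold over all genes. Of the 37 estrogen-induced genes 36 were lower, and 17 passed when adjusted over the list alone.

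As designed limma called 0 genes for E2-BSA+ICI against E2-BSA, with 348 at an unadjusted p below 0.05, and with array set 0, with 1652. The smallest adjusted p from limma with array set was 0.125, for RHOBTB1. The estrogen-induced list was lower, with an adjusted p from limma's camera of 1.43e-16 (adjusted p = 0.872 with an estimated correlation). Ribosome biogenesis genes, lower in 12 of 15, and splicing factor genes, lower in 18 of 22, were also called, with adjusted p from limma's camera of 0.0005 and 2.58e-05 (both adjusted p = 0.872 with an estimated correlation). The fourth list called was immediate early genes, with an adjusted p from limma's camera of 0.00309 (adjusted p = 0.872 with an estimated correlation), and array set ended that call (0.485, limma). Over the 60 genes, the ratio of ICI minus E2-BSA 2 to the E2-BSA response in set 1 had a median of -0.447. The genes were chosen on that set 1 response, so the ratio is not the share of the set 2 response that was lost. With the E2-BSA arrays exchanged it was -0.746, over 42 genes chosen in the same way on set 2 and with the difference taken across the array sets, so genes and arrays changed together. Within set 2, the median of the 60 genes with ICI was 41.8% of that in E2-BSA 2.

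E2-BSA+G15 was compared with E2-BSA for the GPER1 antagonist. On the same 60 genes G15 minus E2-BSA 2 had a median of -0.04, at percentile 4.25 of the random lists, with 41 of 60 below 0. EGR3 differed by -0.35 ± 0.24 and PGR by -0.22 ± 0.19 with array set. Against E2-BSA 2 alone the G15 array differed by -0.15 for EGR3 and -0.08 for PGR. CD81-AS1 differed by -1.23 ± 0.15 and PLAG1 by 0.96 ± 0.14, neither past the threshold. ICI was lower than G15 at 58 of the 60 genes, with a median of -0.53, a comparison added after the data were seen. Of 13 genes linked to GPER signalling, 9 were lower with G15 and 0 passed when adjusted over the list alone. Camera called this list lower as designed, with an adjusted p from limma of 0.0166 (adjusted p = 0.87 with an estimated correlation), and not with array set (adjusted p from limma 0.834).

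As designed limma called 0 genes for E2-BSA+G15 against E2-BSA, with 218 at an unadjusted p below 0.05, and with array set 0, with 1152. Camera called 6 lists as designed, estrogen-induced among them with an adjusted p from limma of 0.00131 (adjusted p = 0.87 with an estimated correlation), and 0 with array set. Of the 37 estrogen-induced genes 30 were lower with array set, and with array set and quantile normalization together camera called the list lower, with an adjusted p from limma of 9.86e-05. Within set 2 this list was not lower: its median against control 2 was 0.608 with G15 and 0.595 in E2-BSA 2. On each of these arrays 11 genes were at least 1 higher. The differences with array set also draw on the set 1 response, with a median of 0.896. The ratio for G15, to the set 1 response, was -0.033 over the 60 genes. It was -0.359 over the 42 genes chosen on set 2 with the E2-BSA arrays exchanged. Within set 2, the median of the 60 genes with G15 was 94.3% of that in E2-BSA 2.

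**Figure D3:**
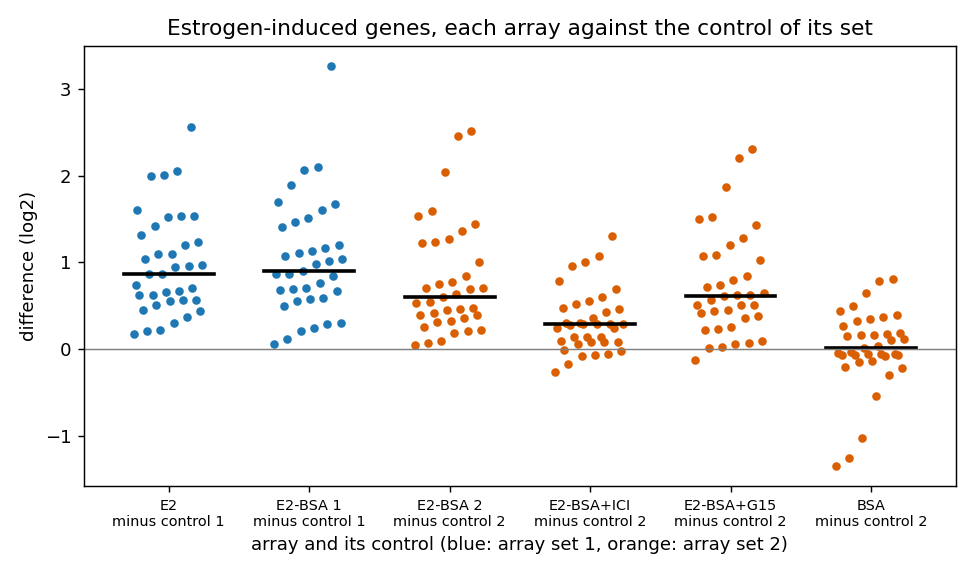
Log2 difference (vertical axis) of the 37 estrogen-induced genes on each array from the control of its own array set, 1 point per gene, with a line at the median. The medians were 0.86 for E2, 0.90 and 0.60 for the E2-BSA arrays, 0.29 with ICI, 0.61 with G15 and 0.01 with BSA.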

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

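The tests of the array sets, and those of ICI other than the test of lost contrast, were chosen only after the result was seen. The tests of the BSA array and of lost contrast were written before.

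Among 13522 probe sets with several gene symbols or none, which the gene-level comparisons left out, 5 were at least 1 higher with E2-BSA than control in both array sets and above both controls. All 5 were also at least 1 higher with E2 than control 1, and 0 were at least 1 higher with BSA, although all 5 were above control 2 there, by 0.289 to 0.998. The one at 0.289 carries the symbols of 2 long noncoding RNA genes and was 1.63 higher in set 1. None was lower by as much.

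The 8 arrays fell into 2 sets. Treatment does not account for the sets, since both same-treatment pairs lay across them. Same-treatment arrays differed at least 1.66 times as much as any different treatments within a set, the BSA array left out. That ratio restates the grouping and is no separate test. A batch of arrays is a candidate explanation. The control pair and the E2-BSA pair differed in the same genes (r = 0.778 across genes). The sets were found from the correlation of the arrays, so this value restates the grouping too. It cannot tell a batch of arrays from a difference between cultures. Labelling or hybridization may contribute, because 24 poly-A spike-in probe sets, whose RNA is not from the cells, differed by a median of -1.02 in the controls and -0.785 in E2-BSA, while 14 hybridization controls moved the other way, by 0.35 and 0.46. A difference between the cultures stays open beside these, and no biological explanation was tested.

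The BSA array stood apart from its set, and the spike-in probe sets had a median of 0.32 for BSA minus control 2, so a labelling difference stays open there too, with no test of its own. A response to the carrier that E2-BSA shares is argued against as the source of most of this difference. BSA minus control 2 and E2-BSA 1 minus control 1 correlated across genes with r = 0.012. The 2 E2-BSA responses, with no shared array, correlated with only r = 0.293, so a small shared part could be missed. A shared carrier response at few genes stays open. Noise of single probe sets stays open, since probe sets of the same gene correlated with r = 0.224, between the bounds set in advance. A wider spread on that array cannot be told apart either: quantile normalization left 0 genes called, below the bound set in advance, and lowered the SD of BSA minus control 2 from 0.403 to 0.254, but it also ended the E2-BSA calls, so the count says nothing particular to BSA. A response to BSA alone stays open and untested with 1 array.

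Genes raised by E2-BSA were lower with ICI. Chance from the choice of genes is argued against by their median of -0.577 on arrays not used to choose them, and an unusual E2-BSA 2 array by the median of -0.531 for ICI minus G15. Lost contrast on the ICI array is argued against: 194 genes within 0.2 between E2-BSA 1 and control 1, but at least 1 higher in control 2 than control 1, had a median of 0.048 for ICI minus E2-BSA 2. An action of the antagonist on the E2-BSA response is a hypothesis that may account for the pattern, but it was found and tested on the same data with 1 ICI array.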

How the results depend on the processing

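Array set as a block, alone or with another setting, quantile normalization for the gene lists, and the correlation with no shared array were chosen after the data were seen. As designed, 0 genes were called in all 7 comparisons under every planned setting except the replicate block. Leaving out each control or E2-BSA array was among these settings and left 1 array in that group. It moved the number of genes at an unadjusted p below 0.05 in each of the 7 comparisons, so that number is not stable. Control and E2-BSA share the replicate numbers 1 and 2, and the deviations of same-numbered arrays correlated with r = 0.778. With the replicate block on those 4 arrays 57 genes were called for E2-BSA against control, as with array set. Groups with 1 array leave no residual, so for this comparison the 2 fits share their differences and their single residual degree of freedom. The match is therefore no separate support. Array set gave 21 for E2 against control, 2435 for BSA against control and 2213 for E2-BSA against BSA, and 0 for the other comparisons.

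With array set in the model, quantile normalization called 0 genes in each of these 4 comparisons. It widened the SD of E2-BSA 1 minus control 1 from 0.244 to 0.366, while that of E2-BSA 2 minus control 2 went from 0.217 to 0.211. The median residual SD went from 0.082 to 0.107. As deposited, the SD over genes was 0.185 to 0.2 in set 1 and 0.304 to 0.505 in set 2. Quantile normalization made these unlike spreads the same, so the lost calls alone do not decide whether the genes changed. On values centred per probe set these SDs are distances from the baseline. Making them alike is therefore not the usual normalization of intensities. For E2-BSA against control the counts were 102 with median centring, which kept all 57 genes, 17 with the probe set of highest mean and 132 over every probe set. Robust eBayes kept 53. For E2 against control they were 36, 3 and 35. BSA against control gave 1549 with the probe set of highest mean and 5572 over every probe set, and E2-BSA against BSA 1317 and 5459. Why the counts moved was not tested beyond these spreads.

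As designed, with an estimated correlation and with fry, 0 lists were called in each comparison. With array set an estimated correlation also called 0, and fry called 1, oxidative phosphorylation genes in E2 against control (adjusted p from limma's fry 0.02, median difference 0.07, 18 of 22 higher). For BSA against control quantile normalization called 2 lists against 1, and array set 0. Array set called 2 lists against 4 for E2-BSA against BSA, 2 against 6 for E2-BSA against E2 and 0 against 6 for G15. Between E2-BSA and E2 the immediate early list turned upward with array set (adjusted p from limma's camera 0.93) and the histone list downward (adjusted p 0.0031, limma). Over the alternatives computed, the adjusted p from limma for the histone list ran from 0.00205 with array set and median centring to 0.985 with an estimated correlation.

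Counts of 2-fold differences at a 1.5-fold threshold and after quantile normalization were 153 and 67 for E2-BSA against control (39 as designed), 777 and 391 for E2 (151), 3721 and 128 for BSA (945), 3677 and 137 for E2-BSA against BSA (854) and 417 and 169 for E2-BSA against E2 (36). The 1.5-fold counts were 926 for ICI (109) and 469 for G15 (40). The larger counts at 1.5-fold follow from the lower threshold. For groups with 1 array, the counts as designed set that array against both sets, so they include the difference between the sets. Within a set, 2-fold counts were 72 for E2 minus control 1, 446 for BSA minus control 2 and 383 for E2-BSA 2 minus BSA. They were 6 for E2-BSA 1 minus E2, and 19 for ICI and 8 for G15 minus E2-BSA 2. For E2-BSA minus control they were 76 in set 1 and 45 in set 2. With the arrays exchanged, over 42 genes in place of 60, the ratio was -0.746 for ICI and -0.359 for G15. The correlation of the E2 and E2-BSA responses was 0.211 with different control arrays and 0.315 with no shared array.

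Of 147 differences of named genes, 12 changed sign under some alternative, none of them past the threshold. The filter at the 70th percentile, the intensity trend and other pseudocounts were not run. Signal over background could not be judged from centred values.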

Other observations

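All values in this part were looked at after the array sets had been seen.

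Some genes differed strongly between the array sets. SLPI, a secreted protease inhibitor gene, was higher in set 2 by 3.04 in the control pair and 4.08 in the E2-BSA pair, TMEM45A by 3.28 and 2.87, and S100A7 by 2.13 and 3.37. SNAI2, a transcription factor gene of the Snail family, was lower in set 2, with differences of -3.60 and -3.24, as were FHL2 (-3.40 and -2.76) and TGFB2 (-2.81 and -2.03). CYP24A1, called above with E2, was also lower in set 2, at -2.22 and -2.73, against 2.41 for E2 minus control 1.

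Several lists moved between the sets. Histone genes had medians of 0.58 in the control pair and 0.85 in the E2-BSA pair, interferon-stimulated genes 0.44 and 0.47, cholesterol synthesis genes 0.46 and 0.41, and p53 targets 0.44 and 0.47. SRF and YAP cytoskeletal targets had medians of -0.38 and -0.34, and MAPK feedback genes -0.46 and -0.31. The estrogen-induced list had 0.01 and -0.25. The 3' minus 5' difference of the GAPDH control probe sets, on centred values, was 0.31 in control 1 and -0.22 in control 2, and 0.14 in E2-BSA 1 and -0.27 in E2-BSA 2. For ACTB it was 0.08 and -0.48 in the controls and 0.29 and -0.32 in the E2-BSA arrays. These are values of single arrays and no explanation for them was tested.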
